A study of Mus musculus with 12 samples.

How the data were processed

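Cervical RNA of 12 samples from CD1 mice at gestation day 15 was measured on Affymetrix arrays, 6 after MPA (1 mg per dam, 48 h) and 6 after ethanol vehicle. Groups and replicate numbers were taken from the sample titles. The labels do not say whether each array came from its own dam, so p values measure the spread between these samples, which may be technical in part. Per the labels' protocols, RNA was extracted with Trizol and a column kit, and biotinylated cDNA was made from a small amount of total RNA after whole-transcript amplification. The deposited value table holds intensity values on a linear scale for 45101 probe sets. Per the submitters' processing notes, the authors used GCRMA, which corrects background by probe sequence, normalizes between arrays and summarises probes; its version is not given in the sources used here. The scale was settled from the values, which run from 4.39 to 77974. Scan files that hold the probe intensities and detection flags were not analysed here, so the level above background can be judged from the table alone. The instrument's text records, deposited beside the table, gave the fluidics station and scan order of each array.

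The planned test foresaw a linear table, and log2 was taken with no pseudocount. Probe sets were named through the platform's annotation: 34958 had 1 gene symbol, 932 had several and 9211 were not listed. Of those with 1 symbol, 34754 matched the RefSeq gene table (GRCm38.p6, used for names only) by Entrez number. A gene was represented by its probe set with the highest mean over the 12 arrays, which left 18193 genes. Genes with a log2 value above 4 on at least 6 arrays were kept, 8794 in all. The values are signals of single probe sets, and levels of different genes were not set against each other.

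MPA was compared with vehicle by limma 3.58.1 (lmFit and eBayes with default settings, R 4.3.3) over all 12 arrays without covariates. Benjamini-Hochberg adjusted p values under 0.05 were called. Differences are MPA minus vehicle on the log2 scale, with the moderated SE. Of 45 lists of genes, 43 had at least 3 measured members and were tested by camera with a preset correlation of 0.01. Camera with an estimated correlation, fry and an exact two-sided permutation test of the mean of each list stand beside it. The smallest p that an exact test of 6 against 6 can give is 0.00216. Correlations across arrays have permutation p values from 100000 draws.

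The gene lists, the main gene and list tests, the filter and the rule for naming genes were chosen before the data were examined. The rule took every called gene, the 10 genes with the smallest unadjusted p since fewer than 10 passed, and from each list described up to 4 called members or, where none passed, the 2 with the smallest p. Genes fixed in advance, among them Pgr, Esr1, Nr3c1, Fkbp5, Dgat1, Has2, Gja1 and Oxtr, were always named where measured. Genes outside the rule are said to be chosen after their values were seen.

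The gene test was tested on simulated data made from the real gene means and spreads, with 8794 genes and 6 against 6 arrays. It recovered 43.3% of 67 genes changed by 0.5 on the log2 scale, 70.1% of 67 changed by 1 and 97.0% of 66 changed by 2, with 1 false call. All were changed in the same run, which eases the adjusted threshold, and genes were drawn independently. The shares therefore do not carry over to data with few changes or with correlated genes. In a second simulation with a single list shifted, camera called that list and 0 others. Genes there were independent as well, which real genes are not. Alternatives covered the filter, probe set summary, normalization, variance model, array weights, test, threshold, pseudocount, fluidics station, RNA quality, replicate number and each array left out. The first principal component as a covariate, the exact test of list means and leaving out MPA 2 with MPA 5 were added after seeing the data. Figures were drawn with matplotlib 3.10.9.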

Results

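Gene expression was measured in the cervix of CD1 mice, an outbred strain, at gestation day 15. Medroxyprogesterone acetate (MPA) is a synthetic progestin that binds the progesterone receptor and, as background, also the glucocorticoid receptor. Dams received 1 mg of MPA under the skin or the matching volume of ethanol vehicle, and tissue was taken after 48 h. Each group had 6 arrays, and their number limits the precision. The median intensity of an array lay between 6.62 in MPA 4 and 6.86 in MPA 5, and between 8582 and 8959 of 18193 genes had a log2 value above 4. No pair of arrays held identical values. Over the 8794 genes tested, Pearson's r between arrays (computed across genes, which are not independent replicates) had a median of 0.963 within MPA, 0.969 within vehicle and 0.968 between the groups.

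The largest share of the variance between arrays did not separate the treatments. The first principal component held 48.5% of the variance and differed between the groups by 9.31 units, MPA minus vehicle, with an exact permutation p = 0.591 (two-sided). Of the 5 components tested, component 3 (8.75% of the variance) and component 4 (6.81%) had an exact permutation p of 0.0476 and 0.00433, unadjusted. MPA 2 lay at -57.3 and MPA 5 at 41.5 on the first component, while the vehicle arrays lay between -32.0 and 20.5. Hoxa10, a homeobox gene of the developing and adult uterus, followed the first component over the 12 arrays with r = 0.949 (permutation p = 1e-05, the smallest that 100000 draws can give) and rho = 0.937 (permutation p = 5e-05); r was 0.954 without MPA 2 and MPA 5. Hoxa11 gave r = 0.927 (permutation p = 6e-05) and rho = 0.846 (permutation p = 0.00111), with r = 0.856 without the same arrays. Both genes were picked after their values were seen, and each enters the first component itself. Both belong to the fibroblast list. Its mean, centred over the 12 arrays, was -1.89 in MPA 2, -0.84 in vehicle 4 and 0.90 in MPA 5. On the same arrays the elastic fibre mean was -1.17, -0.83 and 0.88. The basal epithelial mean was 0.41, 0.45 and -1.08, and the cornified mean 0.39, 0.65 and -1.77. These arrays were picked after their values were seen, and no correlation of list means with the component was tested. Over the 9 relations computed, the Benjamini-Hochberg adjusted permutation p of Pearson's r was 9e-05 for Hoxa10 and 2.7e-04 for Hoxa11. The arrays were washed on 3 fluidics stations. Station 2 held MPA 1, MPA 2, vehicle 5 and vehicle 6, and the other stations held arrays of 1 group each, so that a comparison within a station rests on 2 arrays against 2. With the station as a block, the difference is that same one, and only its spread is estimated from all arrays. The 2 settings are therefore not separate evidence. A station holds too few arrays for a correlation of its own.

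**Figure D1:**
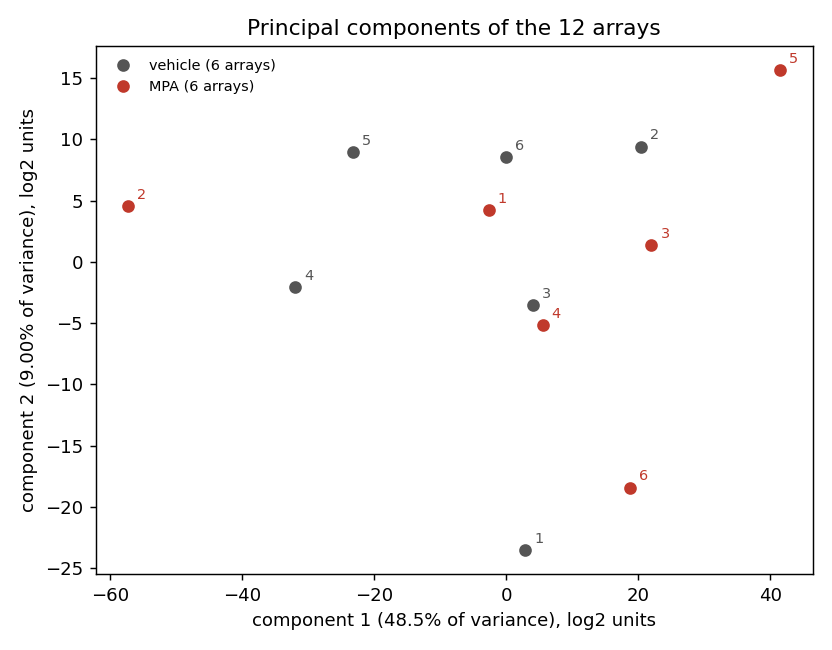
First and second principal components of the 12 arrays over the 8794 tested genes, in log2 units, with each point 1 array numbered by its replicate (vehicle grey, MPA red). The first component runs from MPA 2 at -57.3 to MPA 5 at 41.5, and vehicle arrays lie between them.

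The comparison of MPA with vehicle asks which cervical genes respond to a progestin in pregnancy. Wfdc15b, a member of the whey acidic protein family of small secreted proteins, rose 2.65-fold with MPA, from a log2 intensity of 4.92 ± 0.35 (SD, n = 6) to 6.32 ± 0.31 (SD, n = 6). Fkbp5, a co-chaperone of steroid receptors and a known target of glucocorticoids and progestins, was 1.82-fold higher in MPA, and the lowest MPA array lay above the highest vehicle array. Has2, the hyaluronan synthase that makes the glycosaminoglycan accumulating in the cervix before birth, was lower in MPA by a log2 difference of -1.58, from 9.71 ± 0.51 (SD, n = 6) in vehicle to 8.13 ± 0.78 (SD, n = 6) in MPA. Of these 3 genes, Wfdc15b alone passed the threshold over all genes.

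By limma with Benjamini-Hochberg adjustment, 1 of 8794 genes passed at an adjusted p under 0.05: 1 higher in MPA and 0 lower. Wfdc15b had a log2 difference of 1.40 (SE 0.18, 95% interval 1.02 to 1.79, adjusted p = 0.0332). All 6 MPA arrays lay above all 6 vehicle arrays. At an unadjusted p under 0.05 there were 440 genes, 282 higher and 158 lower in MPA, where chance alone gives 439.7. The groups did not overlap for 30 genes (0.341%), where chance gives 0.216%. The Wfdc15b call was lost when any single array except vehicle 1 was left out, with an adjusted p between 0.0531 and 0.131 (0.0498 without vehicle 1), and within station 2 its log2 difference was 1.76 (SE 0.16, adjusted p = 0.840). No gene passed with the ordinary unmoderated statistic or without the filter on dim genes.

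The 9 further genes among the 10 smallest p values did not pass, and their values are given as measured. The Fkbp5 log2 difference was 0.86 (SE 0.14, adjusted p = 0.149) and that of Has2 was -1.58 (SE 0.35, adjusted p = 0.592). Among secreted immune factors, the chemokine Ccl6 had -0.83 (SE 0.15, adjusted p = 0.422), the chemokine Ccl9 0.93 (SE 0.21) and platelet factor 4, Pf4, 0.68 (SE 0.14). Aif1, a macrophage calcium-binding protein, had 0.93 (SE 0.21), and Npnt, the matrix protein nephronectin, -0.93 (SE 0.21). Heatr5b had 0.41 (SE 0.09) and Tceal9 0.43 (SE 0.10); the adjusted p of these last 6 genes was 0.592. All 10 genes kept their sign within station 2, which is no test of them. They were named on values that include these arrays, and where the groups do not overlap the sign is fixed in any subset. There, the log2 difference was 1.17 (SE 0.22) for Fkbp5, -1.40 (SE 0.24) for Has2, -0.57 (SE 0.18) for Ccl6 and 1.19 (SE 0.16) for Ccl9. In MPA 5 the Has2 value of 6.60 lay apart from the other MPA arrays, which ranged from 8.16 to 8.75, and without that array the Has2 difference was -1.27.

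**Figure D2:**
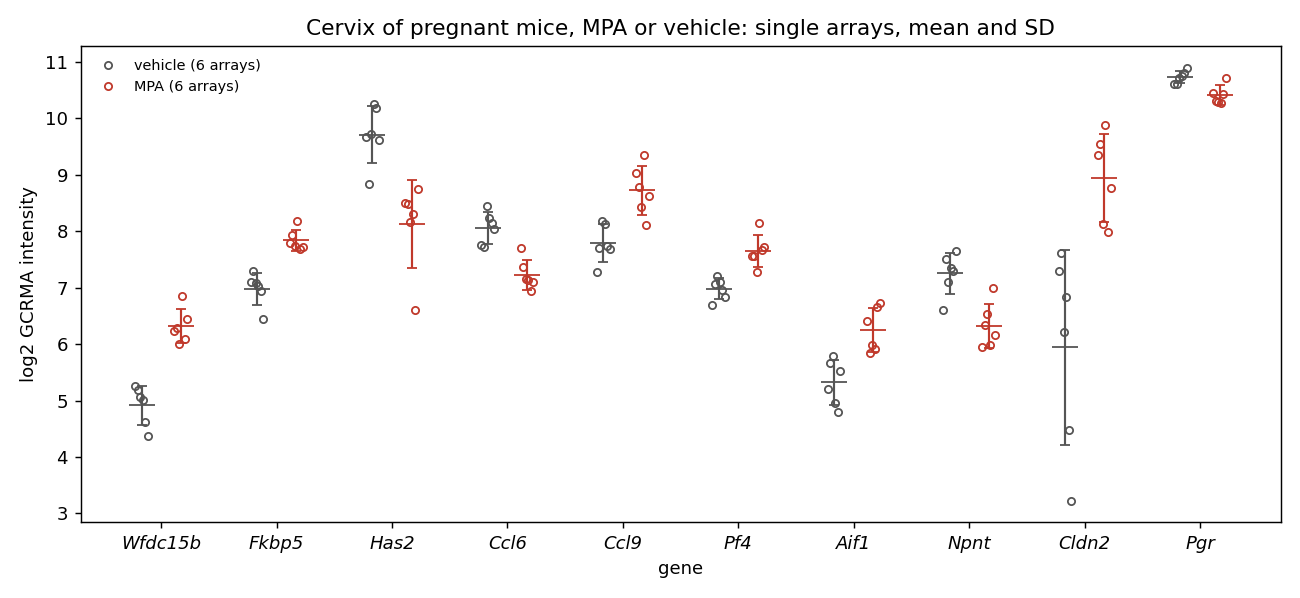
Log2 GCRMA intensity of 10 genes on each array, with open circles for single arrays and bars for the mean and SD of 6 vehicle (grey) or 6 MPA (red) arrays. Wfdc15b alone passed the threshold over all genes; the groups do not overlap for Wfdc15b, Fkbp5, Has2, Ccl6, Pf4, Aif1 and Cldn2.

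None of the steroid receptor genes measured passed. Pgr, the progesterone receptor, had a log2 difference of -0.32 (SE 0.09, adjusted p = 0.863), with 10.41 ± 0.17 (SD, n = 6) in MPA and 10.73 ± 0.11 (SD, n = 6) in vehicle; its 2 other bright probe sets had the same sign. Esr1, the estrogen receptor alpha gene, had 0.13 (SE 0.12), and its 2 other bright probe sets had the opposite sign. Nr3c1, the glucocorticoid receptor gene, had -0.04 (SE 0.09). The adjusted p was 1.00 for both. Among the genes fixed in advance for cervical and uterine function, Gja1, a gap junction protein of the connexin family, had 0.02 (SE 0.09), Oxtr, the oxytocin receptor, -0.24 (SE 0.30), and Dgat1, which makes triglycerides, 0.02 (SE 0.18).

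Gene lists were compared next, to ask which pathways and cell types of the cervix differed. Macrophage and monocyte genes were higher in MPA by a median log2 difference of 0.50, and elastic fibre genes by 0.28. Genes of the basal and cornified layers of stratified epithelium were lower, by medians of -0.31 and -0.46, as were skeletal muscle genes (-0.58) and cholesterol synthesis genes (-0.19). Oxidative phosphorylation genes were higher by a median of 0.08. Of 43 lists tested, camera with its preset correlation called these 7, 3 higher and 4 lower. The estimated correlation of these 7 lists ran from 0.155 in oxidative phosphorylation to 0.579 in elastic fibres, above the preset 0.01. With an estimated correlation camera called 0 lists (1 at an unadjusted p under 0.05), fry called 0 (4 at an unadjusted p under 0.05), and an exact permutation test of the mean of each list called 0 after adjustment (5 at p under 0.05). Of 100 splits of the 12 arrays into 6 and 6, 65 gave at least 7 lists.

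Of 16 macrophage and monocyte genes measured, 15 were higher in MPA and 1 lower (camera adjusted p = 3.67e-05; adjusted p = 0.705 with an estimated correlation). No member passed over all genes; adjusted over the list alone, 4 rose and 1 fell. Aif1 had a log2 difference of 0.93 (SE 0.21) and Tyrobp, a signalling adaptor of myeloid cells, 0.69 (SE 0.19). The 3 others, named after their values were seen, were Mpeg1 with 0.80 (SE 0.27), the lipopolysaccharide co-receptor Cd14 with 0.58 (SE 0.20) and Arg1, the arginase of alternatively activated macrophages, with -1.16 (SE 0.40). The list mean was above the vehicle average in 5 of 6 MPA arrays. Within station 2 the mean of the list differed by 0.04, against 0.42 over all arrays, and the call was lost (camera adjusted p = 0.968, and 0.992 with the station as a block).

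Basal epithelial genes were lower in MPA for 15 of 16 members (camera adjusted p = 1.03e-04; adjusted p = 0.705 with an estimated correlation), and 0 passed adjusted over the list alone or over all genes. Sfn had -1.06 (SE 0.33) and the water channel Aqp3 -0.74 (SE 0.35). Within station 2 Sfn had -0.30 and Aqp3 -0.39, and Sfn exceeded a log2 value of 4 on 3 of 6 MPA arrays. Cornified epithelial genes were lower for 15 of 18 members (camera adjusted p = 3.78e-04; adjusted p = 0.705 with an estimated correlation), again with 0 passing adjusted over the list alone or over all genes. Ivl, the cornified envelope protein involucrin, had -0.93 (SE 0.27) and Sprr1a -1.17 (SE 0.37). Ivl had a mean of 3.99 in MPA and exceeded a log2 value of 4 on 3 of 6 MPA arrays. Within station 2 Ivl had -1.17 and Sprr1a -1.17. MPA 5 had the lowest epithelial values: its cornified score was -1.77, where the other MPA arrays ranged from -0.20 to 0.39. Without MPA 5 the mean difference of the cornified list went from -0.43 to -0.11 (camera adjusted p = 0.0889) and that of the basal list from -0.35 to -0.17. With each array left out in turn, the adjusted p of the cornified list ran from 7.44e-05 to 0.0889. Within station 2 the means were -0.11 and -0.01, the basal median turned to 0.12, and both calls were lost (camera adjusted p = 0.597 and 0.946, and 0.698 and 0.889 with the station as a block).

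Skeletal muscle genes were lower for 10 of 12 members (camera adjusted p = 4.92e-04; adjusted p = 0.705 with an estimated correlation), with 0 passing adjusted over the list alone or over all genes. The troponin Tnnc2 had -1.18 (SE 0.51) and the myosin Myh8 -1.49 (SE 0.67). The mean difference of the list was -0.61, and -0.39 without vehicle 1 (camera adjusted p = 0.0247). Within station 2 it was -0.74. The call was lost in 5 of 16 alternatives, among them array weights (-0.34). Over the alternatives the mean difference ran from -0.74 to -0.27 and the adjusted p from 1.56e-05 to 0.705. Cholesterol synthesis genes were lower for 14 of 17 members (camera adjusted p = 0.00167; adjusted p = 0.705 with an estimated correlation) and 0 passed adjusted over the list alone or over all genes. Hsd17b7 had -0.56 (SE 0.22) and Pmvk -0.27 (SE 0.14). The mean difference of this list went from -0.17 to -0.03 without MPA 5 (camera adjusted p = 0.245), and it turned to 0.22 within station 2. There the list passed as higher in MPA (camera adjusted p = 0.0476), which it did not with the station as a block (camera adjusted p = 0.135).

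Among 45 oxidative phosphorylation genes, 39 were higher in MPA (camera adjusted p = 8.91e-04; adjusted p = 0.705 with an estimated correlation), and 0 passed adjusted over the list alone or over all genes. The ATP synthase subunits Atp5e and Atp5o had 0.57 (SE 0.20) and 0.27 (SE 0.10). The mean of this list was higher in MPA with an exact permutation p = 0.0368 (adjusted p = 0.372 over the 43 lists), above the vehicle average in 6 of 6 MPA arrays, and its difference was 0.07 within station 2, where the call was lost (camera adjusted p = 0.597, and 0.494 with the station as a block). All 11 elastic fibre genes were higher in MPA (camera adjusted p = 0.0490; adjusted p = 0.705 with an estimated correlation). Ltbp1, which binds latent TGF-beta, passed adjusted over the list alone with 0.49 (SE 0.12), and 0 members passed over all genes; Emilin1 had 0.42 (SE 0.19), which turned to -0.03 within station 2. The elastic fibre mean turned from 0.29 to -0.63 within station 2. There the list passed as lower in MPA (camera adjusted p = 0.0247, and 0.00770 with the station as a block). The call over all arrays was lost without any 1 of MPA 3, MPA 4, MPA 5, MPA 6, vehicle 1 or vehicle 4, with adjusted p up to 0.414. With each array left out in turn, the mean ran from 0.14 without MPA 5 to 0.55 without MPA 2.

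**Figure D3:**
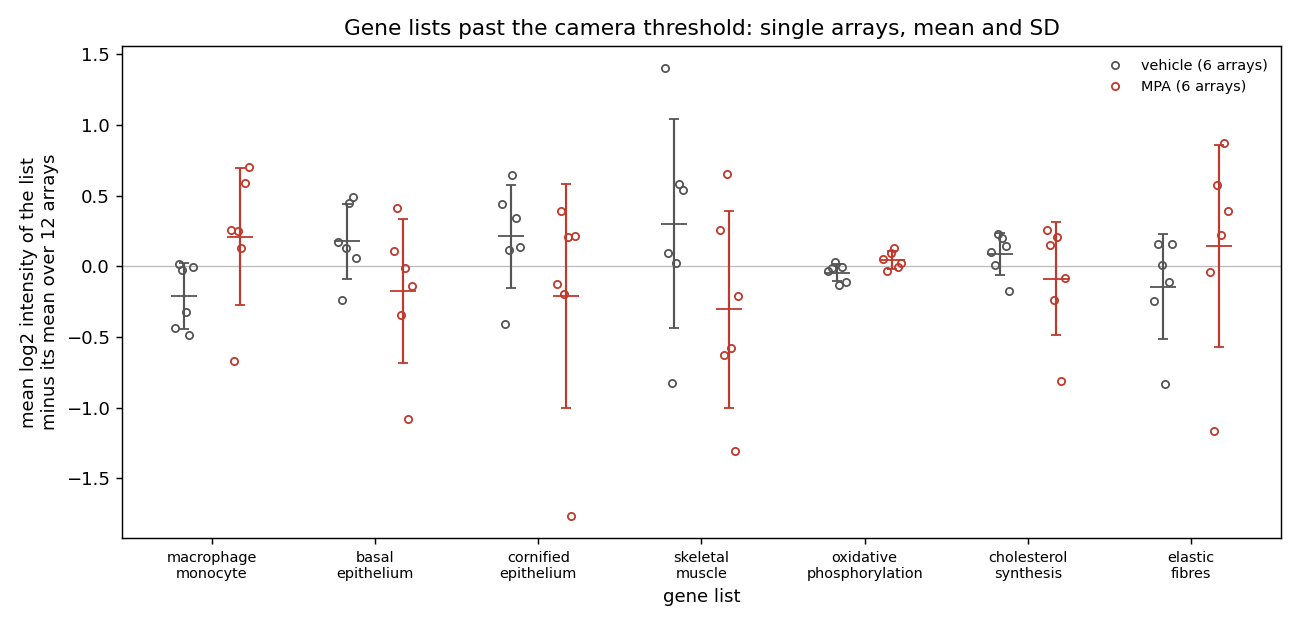
Mean log2 intensity of each of the 7 lists called by camera with its preset correlation, per array and centred on the mean of 12 arrays, with bars for the mean and SD of 6 vehicle (grey) or 6 MPA (red) arrays. The groups overlap for every list drawn, and MPA 5 is lowest for the cornified list at -1.77.

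The lists closest to the action of a progestin did not pass in the main test. Of 27 glucocorticoid-responsive genes, 19 were higher in MPA, with a median of 0.11 (camera adjusted p = 0.0529), and of 19 progesterone receptor targets, 15 were higher, with a median of 0.14 (camera adjusted p = 0.119). Adjusted over the list alone, Fkbp5 passed in both, and Sgk1, a kinase of sodium transport with a log2 difference of 0.39 (SE 0.11), passed in the second; 0 members of either passed over all genes. MPA 2 lay apart from the other MPA arrays in both lists; without it the mean differences were 0.32 and 0.37, and both passed with the preset correlation (camera adjusted p = 0.00436 and 0.00295). Over all arrays, both had an adjusted p = 0.705 with an estimated correlation, which was not run without MPA 2. Both lists also passed without vehicle 2, and the glucocorticoid list without MPA 1 or vehicle 6. Of 16 other alternatives, the glucocorticoid list passed in 5 (lowest camera adjusted p = 0.0151) and the progesterone list in 1 (camera adjusted p = 0.0346). With each array left out in turn, the adjusted p ran up to 0.257 and 0.477, and within station 2, which holds MPA 2, the means turned to -0.06 and -0.16. Of 20 estrogen-responsive genes, 10 were higher and 10 lower, and 0 passed adjusted over the list alone; Pgr led it, followed by Padi2 with -0.63 (SE 0.20).

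Has2 passed adjusted over the list alone among 14 hyaluronan and proteoglycan genes, of which 10 were higher in MPA. Over all arrays this list had a median of 0.13 and did not pass (camera adjusted p = 0.529; adjusted p = 0.905 with an estimated correlation). Within station 2 its mean was -0.67 (camera adjusted p = 0.00339; up to 0.998 over the alternatives). Sdc2 had 0.33 (SE 0.18), which turned to -0.00 within station 2. Cldn2, the pore-forming claudin, had 3.00 (SE 0.70), an 8.01-fold higher level in MPA with no overlap between groups. It passed adjusted over the list alone among 25 junction genes but not over all genes (adjusted p = 0.592); Dsp, a desmosomal protein, had -0.32 (SE 0.17). With the fluidics station as a block, the Cldn2 difference was 5.60 (SE 0.64, adjusted p = 0.0316), and within station 2 alone it did not pass (adjusted p = 0.840); over the alternatives its adjusted p ran up to 0.964. Both fits rest on MPA 1 and MPA 2 against vehicle 5, with a Cldn2 value of 4.47, and vehicle 6, with 3.23, under the log2 value of 4, so the size is uncertain. Of 34 fibrillar collagen and crosslinking genes, 27 were higher in MPA with 0 passing adjusted over the list alone (camera adjusted p = 0.188); Pcolce2 had -0.55 (SE 0.28) and Tnxb 0.86 (SE 0.44). Of 21 metalloproteinases and inhibitors, 18 were higher with 0 passing adjusted over the list alone (camera adjusted p = 0.149); Plat had 0.80 (SE 0.30) and Adam8 -0.43 (SE 0.26). Tnxb and Plat each exceeded a log2 value of 4 on 2 of 6 vehicle arrays. Within station 2 Pcolce2 had -0.71, Tnxb 0.14, Plat 0.76 and Adam8 -0.15. With 1 array left out, the weakest differences were -0.36, 0.65, 0.66 and -0.23, in the same order. Without MPA 2 the mean difference of the collagen list was 0.50 and that of the metalloproteinase list 0.41, and both passed with the preset correlation. Over all arrays they had an adjusted p = 0.913 and 0.746 with an estimated correlation, with correlations of 0.627 and 0.258. Both also passed without vehicle 2. With each array left out in turn, the adjusted p ran up to 0.929 and 0.626. Within station 2 the means turned to -0.74 and -0.23 (camera adjusted p = 1.32e-05 and 0.360). There the collagen list passed as lower in MPA, opposite to its direction without MPA 2.

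No list of contraction or inflammation passed apart from the macrophage and monocyte list. Of 11 contraction-associated genes, 8 were higher in MPA, and of 22 smooth muscle markers, 15 were higher, with 0 passing adjusted over the list alone in either; neither list passed. Without MPA 2 the mean differences were 0.44 and 0.42, where the lists had 0.14 and 0.07 over all arrays, and both passed with the preset correlation. Over all arrays they had an adjusted p = 0.968 and 0.991 with an estimated correlation, with correlations of 0.492 and 0.926. With each array left out in turn, the adjusted p ran up to 0.988 and 0.987, and within station 2 the means turned to -0.44 (camera adjusted p = 0.279) and -0.69 (camera adjusted p = 0.00103). Without MPA 3, MPA 5, vehicle 4 or vehicle 5 the smooth muscle mean turned negative, with a lowest value of -0.08; the contraction mean turned to -0.04 without vehicle 4. Kcnma1 had 0.55 (SE 0.42), Cacna1d 0.18 (SE 0.17), Casq2 0.51 (SE 0.44) and Ldb3 0.23 (SE 0.33). Within station 2, Kcnma1 turned to -0.11, Casq2 to -0.26 and Ldb3 to -0.52, while Cacna1d went up to 0.39. With 1 array left out, the lowest differences were 0.34 for Kcnma1, 0.31 for Casq2, 0.05 for Ldb3 and 0.10 for Cacna1d. In the prostaglandin list, 8 of 11 genes were higher (camera adjusted p = 0.119); Abcc4, an exporter of prostaglandins, had 0.61 (SE 0.18) and the synthase Ptges 0.37 (SE 0.13), and neither passed adjusted over the list alone. Among 19 cytokines and chemokines, Ccl9 rose and Ccl6 fell when adjusted over the list alone (camera adjusted p = 0.309). Nfkbiz, an inducible NF-kappaB regulator, had -0.43 (SE 0.11) and was the single member to pass adjusted over the list alone among 14 Toll-like receptor signalling genes (camera adjusted p = 0.893). Median, mean and test differed in sign for 9 lists: hyaluronan, junctions, estrogen-responsive, mucins, hypoxia, endothelium, neural, Toll-like receptor, and water and ion transport.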

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

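Among the tests below, several were chosen only after the result was seen. They are the maternal blood test, the share of the first component between the groups and the station test by gene. The tests with the first component or the Gapdh difference as a covariate were also chosen then. In 28 of 216 groups of 6 arrays examined, the highest or lowest array lay apart from the others by Dixon's test at a chance of 5%, where chance gives about 10.8. The arrays concerned are named with their values at the end of this part.

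The count of 1 called gene was met by 5 of 100 splits of the 12 arrays, the real split included, and the highest other split also gave 1, so chance cannot be excluded. The count of 7 lists was met by 65 of 100 splits; the highest other split gave 24 lists, several times the real count. Chance cannot be excluded for the lists either. A structure of the samples that crosses the groups is also seen in the genes at an unadjusted p under 0.05: 440 in the real split and up to 1833 in another.

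The pattern seen first is the component that holds 48.5% of the variance. At its ends, MPA 2 and MPA 5, the fibroblast and basal epithelial means lay in opposite directions, and tissue makeup as its cause was not tested. RNA quality stays open as a part of the component. After the Gapdh 3' minus 5' difference was regressed out of every gene, the first component held 48.4% of the variance left. That share was at least 42.5% with any single array left out. A share of what the regression left cannot show how much of the original component followed RNA quality. The original component followed the Gapdh difference with r = 0.41 (permutation p = 0.179) and rho = 0.52 (permutation p = 0.085). Without MPA 2 and MPA 5, r was 0.38. Treatment also stays open as a part of the first component: 3.30% of its variance lay between the groups, and up to 29.8% when an array was left out. A candidate explanation is the level of the reproductive tract at which tissue was dissected, but the test set in advance was void, since Hoxa13 was near the floor on all 12 arrays and Hoxd13 exceeded a log2 value of 4 on 3; their mean followed the component with r = -0.20 (permutation p = 0.533) and rho = -0.30 (permutation p = 0.346), with r = -0.57 without MPA 2 and MPA 5.

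The next pattern is the lower level of Hbb-y, an embryonic globin, and Afp, alpha-fetoprotein, in MPA, with log2 differences of -2.71 (SE 0.76) and -1.30 (SE 0.44), both past the threshold adjusted over the list alone and neither over all genes (adjusted p = 0.863 and 0.897). Within station 2 the differences were -0.44 (SE 0.88) and -0.58 (SE 0.51), and the highest Hbb-y value, 9.88, was that of vehicle 1. Against maternal blood, the 95% interval of the adult globin Hba-a2 difference had its lower end at -0.88, above -1.35, which is 0.5 of the Hbb-y difference. That cut is uncertain, since the Hbb-y 95% interval ran from -4.35 to -1.06. The Hbb-y mean in MPA, 3.88, was also under a log2 value of 4. Hba-a2 followed Hbb-y with r = 0.256 (permutation p = 0.423), and with r = 0.752 without vehicle 1 and vehicle 2. Maternal blood therefore stays open. Yolk sac or fetal RNA may be a source: the mean of 15 markers followed Hbb-y with r = 0.894 (permutation p = 1.9e-04) and rho = 0.790 (permutation p = 0.00306), and r was 0.646 without vehicle 1 and vehicle 2. This stays open, because 13 of the 15 markers, among them the abundant Alb, Apoa1 and Apoa4, stayed at or under a log2 value of 4 on every array, and Ttr, the 1 marker that varied above that level in some arrays and not others, reached 8.76 in vehicle 1 and 4.49 in the next array.

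The last pattern is the set of Wfdc15b, Fkbp5 and Has2 differences, for which a response to MPA stays among the open explanations, as untested. With the first component as a covariate, at least 90.9% of each difference was left, and with the Gapdh 3' minus 5' difference at least 96.1%. The groups differed little along the component (exact permutation p = 0.591), and their Gapdh values overlapped. Either covariate could therefore take away little, and high shares were likely from the start. The shares show only that these measures, as taken, do not carry the differences. Other differences in tissue or RNA stay open. Under the first covariate the Wfdc15b difference stayed at 1.40, its SE went from 0.178 to 0.183 and its adjusted p from 0.0332 to 0.0503, so the call ended through the wider SE and the degree of freedom spent on the covariate; under the Gapdh covariate the call also ended, with a difference of 1.35 (SE 0.18) and an adjusted p = 0.115. With the station as a block, Wfdc15b kept 125.4% (SE 14.3) and Fkbp5 135.8% (SE 19.4), so neither difference shrank within station 2. That fit rests on 2 arrays against 2. The pattern was also picked on values that include these arrays, with no overlap between the groups. The shares therefore cannot decide on station for these genes. The Wfdc15b difference went from 1.40 (SE 0.18) to 1.76 (SE 0.25). Its adjusted p went to 0.105, the call ending through the wider SE. Has2 kept 88.8%, but with an SE of 31.7%, so station and group cannot be told apart for it either.

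Among array measures, the Gapdh 3' minus 5' log2 difference was 5.61 in MPA 6, where the other MPA arrays ranged from 4.14 to 4.64, and 4.94 in vehicle 1, where the others ranged from 4.25 to 4.37. The bioB spike had a log2 value of 9.60 in MPA 6, against 11.13 to 11.60 in the other MPA arrays. MPA 2 had 8582 genes above a log2 value of 4, against 8854 to 8959.

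Single genes with an array apart were Has2 at 6.60, Ivl at 3.04 and Myh8 at 2.66 in MPA 5, Gja1 at 11.60 in MPA 6 and Kcnma1 at 5.87 in MPA 2. In vehicle, they were Dgat1 at 6.17 in vehicle 5, Oxtr at 4.05 in vehicle 4 and Emilin1 at 4.17 in vehicle 1.

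List scores, centred over the 12 arrays, lay apart in MPA 2 for smooth muscle (-1.71), fibroblasts (-1.89), fibrillar collagen (-1.48), contraction-associated genes (-1.41), steroid metabolism (-1.14), progesterone receptor targets (-0.78), estrogen-responsive genes (-0.47), glucocorticoid-responsive genes (-0.42), the prostaglandin pathway (-0.39), hypoxia and glycolysis (-0.35) and erythroid genes (0.042). The cornified epithelial score was -1.77 in MPA 5. In vehicle 4 the endothelial score was -0.71 and the hyaluronan and proteoglycan score -0.58. In vehicle 6 the immediate early gene score was 0.53 and the ribosomal protein score -0.10.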

How the results depend on the processing

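The settings with the first component as a covariate, without both MPA 2 and MPA 5, and with exact permutation of list means were chosen after seeing the data. The count of genes went from 1 to 0 without the filter on dim genes, with every probe set by itself, with the statistic without moderation, within station 2, with the Gapdh 3' to 5' covariate, at a threshold of 0.01, with the first component as a covariate and without both MPA 2 and MPA 5; the Wfdc15b adjusted p under alternatives with a test ran from 0.0208 to 0.840; the cause was not tested, except that the SE of Wfdc15b widened from 0.178 to 0.183 both with the first component (1.40) and with the Gapdh covariate (1.35). It stayed at 1 in 10 others; with the fluidics station as a block the 1 gene was Cldn2 (5.60, adjusted p = 0.0316), not Wfdc15b. Leaving out 1 array gave 0 to 1 genes, with 1 only without vehicle 1. The count of lists went from 7 to 0 with fry, with an estimated correlation and with exact permutation of list means. The estimated correlation of these 7 lists ran from 0.155 to 0.579, against the preset 0.01. The count went to 11 without the filter. It went to 16 with the station as a block, within station 2 and without both MPA 2 and MPA 5. Leaving out 1 array gave 6 to 16 lists, with 16 without MPA 2 and 12 without vehicle 2. For the settings other than the estimated correlation, the cause was not tested. Within station 2 and with the station as a block, cholesterol synthesis reversed to 0.22 and elastic fibres to -0.63. Both passed in the new direction within station 2, and elastic fibres also with the block. The macrophage, basal, cornified and oxidative phosphorylation lists lost their call in both settings. Of the 7 lists skeletal muscle alone kept its call and direction, so most of the 16 lists are others. Of 1606 values of the 58 other named genes, 1573 kept their sign and side of the threshold and 32 changed sign without a call. None of the 58 passed in the main test, and the settings share most arrays. The tally is therefore no test of these genes.

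The labels do not say that the replicate numbers pair the arrays. Arrays with the same number correlated between -0.60 and 0.05 after their group means were removed. That shows no sign of pairing and cannot exclude it. The replicate block gave 0 genes and 7 lists. Signal over background limits the comparison to 8794 of 18193 genes; the others were tested only without the filter.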

Other observations

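Among the tests below, the exact permutation of list means was chosen only after the result was seen. Secretory and mucosal immune genes with large but variable values are not described above. Of 4 B and plasma cell genes, Jchain and Igha, the joining chain and heavy chain of mucosal IgA, had log2 differences of 1.97 (SE 0.59) and 1.92 (SE 0.70) and both passed adjusted over the list alone, while 0 passed over all genes (limma adjusted p = 0.863 and 0.939). Jchain exceeded a log2 value of 4 on 3 of 6 vehicle arrays. The 2 other members, named after their values were seen, were lower: Sdc1 had -0.23 (SE 0.21) and Xbp1 -0.02 (SE 0.16). The list mean was higher in MPA with an exact permutation p = 0.0281 (adjusted p = 0.372 over the 43 lists). Lcn2, the iron-binding lipocalin of neutrophils and epithelium, had 2.33 (SE 0.90), and Hp had 0.85 (SE 0.46), which turned to -0.86 within station 2; the mean of 4 neutrophil genes was higher in MPA with an exact permutation p = 0.0130 (adjusted p = 0.279), but 2 of the 4, Ltf with -0.09 (SE 0.15) and Stfa3 with -0.32 (SE 0.54), both named after their values were seen, were lower. In the list of mucins and secretory epithelium, Gcnt3, which builds mucin side chains, had 0.66 (SE 0.20), and 0 members passed adjusted over the list alone.

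Among 14 water and ion transport genes, Kcne3, a potassium channel subunit, had 1.03 (SE 0.30) and Cftr, the chloride channel, -0.97 (SE 0.37), with 0 passing adjusted over the list alone. Within station 2 the differences were 2.17 (SE 0.30) and -0.62 (SE 0.30). Of 24 genes of the endoplasmic reticulum stress response, 20 were higher in MPA with a median of 0.09 (camera adjusted p = 0.0583) and 0 passed adjusted over the list alone. This list passed within station 2 (mean difference 0.19, camera adjusted p = 0.0107) and with the station as a block (0.00985), which is the same difference and not a separate result. It passed with a stricter filter, with array weights and without both MPA 2 and MPA 5, which was chosen after seeing the data. It also passed without MPA 5, vehicle 1 or vehicle 3. Its adjusted p ran from 0.00385 to 0.705 over the alternatives and from 0.00106 to 0.316 with each array left out in turn; over all arrays it had an adjusted p = 0.705 with an estimated correlation.

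The mean of 5 erythroid genes was lower in MPA with an exact permutation p = 0.00866 (adjusted p = 0.279), below the vehicle average in 6 of 6 MPA arrays, while camera gave an adjusted p = 0.451. The median was -0.09, with 2 members higher and 3 lower, and the mean of -0.56 is carried by Hbb-y, which fell when adjusted over the list alone; Tfrc, the transferrin receptor, had 0.27 (SE 0.16). The 3 others, named after their values were seen, were Hba-a2 with -0.33 (SE 0.25), Hbb-b2 with -0.09 (SE 0.38) and Tmod1 with 0.09 (SE 0.09). Of 3 decidual and placental genes, Afp fell when adjusted over the list alone, and Peg10 had -0.31 (SE 0.29).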
